A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

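RNA levels were measured in budding yeast (Saccharomyces cerevisiae) on 18 Affymetrix yeast S98 arrays. Per the labels, the strains were a W303-1A wild type, a strain with FAR1 deleted by a HIS3 cassette, and a strain that overexpressed Myc-tagged FAR1 from a plasmid with a tetracycline-type promoter. Each strain grew exponentially in synthetic complete medium with glucose or with ethanol as carbon source. The labels give 3 independent cultures for each of the 6 groups. Per the labels' protocols, total RNA was labelled with biotin by the One-Cycle procedure, and the scans were processed with GCOS, the array maker's software. The GCOS version, its signal algorithm and any scaling target are not given in the sources used here.

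The deposited values are probe set signal intensity on a linear scale, 1 value per probe set and array, with 9335 probe sets. The median intensity of an array ranged from 8.5 to 23.8 and the highest from 4066 to 6642. There were 1955 values of 0 in the table. Mean intensities with 2% trimmed at each end ranged from 35.3 to 77.9, a ratio of 2.20, so the arrays had not been brought to a common level within the 5% tolerance set beforehand. The arrays hold no count from which a depth follows, and their number limits the precision.

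The 60 control probe sets were kept out of the gene tests. Of the 9275 others, 6504 matched 1 gene in the probe table, 328 matched several genes and 2443 had no gene there. The latter 2 kinds were left out of the gene tests, except where an alternative says otherwise. The 6504 probe sets stood for 5656 genes, of which 315 had several probe sets, and the probe set with the highest mean over the 18 arrays was used. All 6504 gene identifiers matched the reference gene table, and 0 symbols needed an update. Of 296 tested genes with several probe sets, 6 had probe sets called in opposite directions between ethanol and glucose in the wild type, 3 in the deletion strain and 12 in the overexpression strain, and 0 in the other comparisons. No genome build is named in the sources used here, so no coordinates are given.

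Values were taken as log2 of the intensity plus a pseudocount of 0.4, the 10th percentile of all deposited values, and quantile normalized. The rule written before the data were examined chose quantile normalization if the trimmed means differed by more than the tolerance. It therefore became the main setting, and the deposited scale an alternative added after the data were seen. A gene was tested if its value lay above the 20th percentile of its array in at least 3 arrays, which left 5545 genes. Fold changes of genes near the floor depend on the pseudocount.

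A linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend. It had 12 residual and 5.59 prior degrees of freedom. The model gave 9 comparisons, each with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. These were deletion against wild type and overexpression against wild type in each carbon source, ethanol against glucose in each strain, and the difference of each strain's effect between ethanol and glucose. Replicate numbers were not used as a block, because the labels do not say that cultures with the same number were grown together. Errors of log2 changes are standard errors from this model, with 3 arrays per group.

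There were 35 gene lists fixed before the data were examined. They covered growth (cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, translation factors, cytosolic tRNA synthetases, growth regulators, mitochondrial ribosomal proteins), cell type and cycle (pheromone response, alpha cell specific genes, a cell specific genes, sporulation, stationary phase, G1/S targets of SBF and MBF, M/G1 targets, the G2/M CLB2 cluster, histones), carbon use (glycolysis and fermentation, hexose transporters, gluconeogenesis with the glyoxylate cycle and ethanol use, tricarboxylic acid cycle, respiratory chain and ATP synthase, fatty acid oxidation and peroxisome), stress (Msn2/Msn4 stress genes, storage carbohydrates, heat shock proteins and chaperones, proteasome, cell wall integrity, hypoxic and anaerobic) and nutrients (Gcn4 amino acid biosynthesis, methionine and sulfate, purine and one-carbon, uracil biosynthesis, phosphate, iron uptake, ergosterol). Each list was tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the 35 lists of a comparison. The intensity trend of the gene tests was also used in camera. The design written beforehand did not specify this, and an exploratory run without the trend in camera gave slightly different counts of lists. Every list was also tested with an estimated correlation, with ranks and with fry, which asks whether a list's genes move on balance one way.

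The genes named in the report follow a rule written before the data were examined. It takes FAR1. It takes up to 10 of the largest rises and 10 of the largest falls past the threshold without overlap between replicates, or 5 each way for the differences between carbon sources and for the carbon source comparisons in the FAR1 strains. It takes up to 3 members of each called list and 2 of each other list. It takes the marker genes HIS3, ADE2, LEU2, TRP1, URA3 and CAN1. It takes CLN1, CLN2, CLN3, CLB5, CDC28, SIC1, SFP1 and STE12, given as values whatever they did. Genes without known function and those with smaller changes were dropped to keep each comparison short. Genes outside the rule are said to be chosen after their values were seen.

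Control probe sets for RNA quality, rRNA and spike-ins were compared between groups with two-sided exact permutation tests, adjusted over 42 tests. With 3 arrays against 3 the smallest possible p is 0.1. Overlaps between comparisons that share wild type arrays were set against the mean of 100 simulated draws without any strain effect, drawn anew for the fits without doubtful arrays and with the spike-in block. Tested on simulated data with the deletion against wild type design in glucose, 16 of 50 genes changed 1.5-fold were called, 42 of 50 changed 2-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold. In that simulation 11 of 174 called genes were unchanged, a list shifted on purpose was called with 0 other lists, and a comparison with nothing changed gave 0 genes and 0 lists. The simulated genes varied independently of each other, and the single changed genes were drawn from those above the floor. The simulation therefore does not test lists of correlated genes or changes near the floor.

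Alternatives listed beforehand were no low filter, a filter at the 40th percentile in at least 3 arrays, a pseudocount at the 25th percentile of all values (2.9) or of 1, centred array medians, all non-control probe sets, probe sets shared within a list added as members, replicate number as a block, each array left out in turn, only the groups compared, robust eBayes, no intensity trend, and the other list tests. Alternatives chosen after seeing the data were the deposited scale, a block for 2 sets of arrays told apart by a spike-in ratio, and fits without either or both of 2 pairs of doubtful arrays described in the report. Arrays were kept in the groups the labels give throughout. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.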

Results

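The series measured RNA levels in wild type budding yeast, a far1 deletion strain and a FAR1 overexpression strain, each grown in glucose or in ethanol. FAR1 codes for an inhibitor of cyclin-dependent kinase. The stated question was how FAR1 dosage affects the transcription pattern in each carbon source, and the title also names RNA and protein content and Sfp1, a regulator of ribosome synthesis. Each of the 6 groups had 3 arrays from independent cultures. The median deposited intensity of an array was 8.5 to 11.3 in wild type glucose, 14.4 to 19.5 in wild type ethanol, 11 to 16 in deletion glucose, 12.6 to 23.8 in deletion ethanol, 11.2 to 15.4 in overexpression glucose and 16.3 to 19 in overexpression ethanol. Replicates of a group correlated across genes at r = 0.946 to 0.979, and no pair shared more than 4.04% identical values. In a principal component analysis of the 18 arrays the first component held 63.6% of the variance, the second 8.05% and the third 4.31%. Genes are not independent replicates, so correlations across genes describe similarity only.

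FAR1 (YJL157C) itself was measured first. In glucose its intensity was 19.7, 27.3 and 22.8 in the wild type, 4.9, 7.0 and 4.1 in the deletion strain and 1020, 966 and 557 in the overexpression strain. In ethanol it was 29.3, 17.9 and 25.5 in the wild type. The arrays labelled deletion in ethanol read 4.8, 5.3 and 2596, and those labelled overexpression in ethanol read 2554, 2722 and 3.3. Array 3 of each of these 2 groups therefore held a FAR1 signal opposite to its label. Both arrays were kept in their labelled groups, and counts of genes in ethanol are also given without this pair. Because the pair widens the spread of FAR1 in the shared model, no FAR1 change passed the test with all 18 arrays. The log2 change from wild type was −2.60 ± 2.17 (SE, n = 3) in deletion glucose (adjusted p = 0.640 in limma) and 4.51 in overexpression glucose (adjusted p = 0.225). It was 1.01 in the arrays labelled deletion in ethanol (adjusted p = 0.980) and 3.89 in those labelled overexpression in ethanol (adjusted p = 0.550). Without the pair the 4 values were −2.59 (adjusted p = 5.80e-06), 4.56 (4.50e-09), −2.16 (1.85e-04) and 7.19 (2.47e-11).

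**Figure D1:**
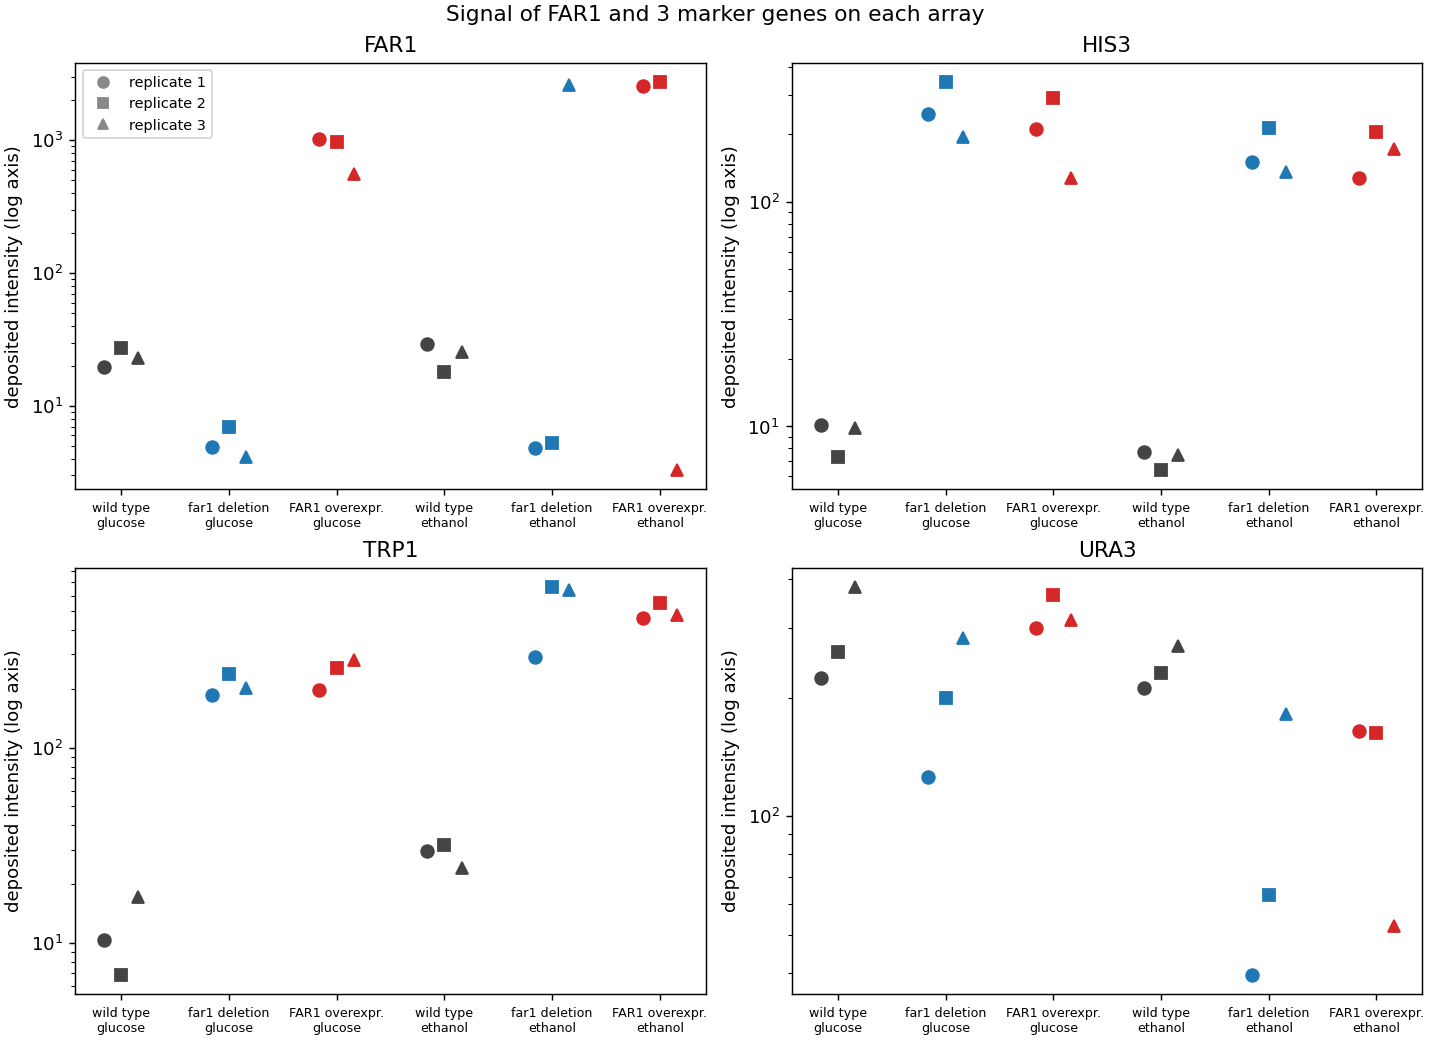
Deposited intensity of FAR1, HIS3, TRP1 and URA3 on each of the 18 arrays, on a log axis, by group, with marker shape for the replicate. Array 3 of the deletion and of the overexpression strain in ethanol read 2596 and 3.3 for FAR1, opposite to the other arrays of their groups.

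The marker genes HIS3 and TRP1 set both FAR1 strains apart from the wild type. HIS3 (YOR202W), a histidine biosynthesis gene, had an intensity of 6.4 to 10.2 in the 6 wild type arrays and 127 to 340 in the 12 others. Its log2 rise over wild type was 4.09 ± 0.22 in deletion glucose, 3.78 in overexpression glucose, 4.47 in deletion ethanol and 4.51 in overexpression ethanol. TRP1, a tryptophan biosynthesis gene, rose by 3.61 ± 0.28, 3.86, 4.22 and 4.15 in the same order. All 8 adjusted p-values lay at or below 6.31e-07. URA3, of uracil synthesis, read 39.6, 63 and 182 in the arrays labelled deletion in ethanol and 164, 163 and 52.7 in those labelled overexpression in ethanol. CDC42, which codes for a polarity GTPase and was chosen after its values were seen, read 175, 311 and 1087 in the former and 1466, 1778 and 213 in the latter. Genes specific to alpha cells were expressed although the labels call the strains MATa. MF(ALPHA)1, a pheromone gene, read 446 to 2399 and the receptor gene STE3 38.4 to 136. Of the a cell genes, STE2 read 0.1 to 2.4, ASG7 0.1 to 0.5, AGA2 0.3 to 2.5 and MFA1 0.2 to 9.1 over its probe sets.

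RNA quality controls stood apart in overexpression glucose arrays 1 and 3. Their actin 3′ probe set read 1389 and 1399 while the 5′ probe set read 4.8 and 2.6. The log2 ratio of 3′ to 5′ actin was 8.06 and 8.87 there and 0.32 to 1.04 in the other 16 arrays. The group means of this ratio differed by 4.98 between overexpression and wild type in glucose (two-sided exact permutation p = 0.4, adjusted p = 0.542). The smallest p that 3 against 3 arrays allow is 0.1. SRB4, another control gene, had log2 ratios of 3.54 and 3.89 on the same 2 arrays. Of the other control measures, some differed between FAR1 strains and wild type without overlap (exact permutation p = 0.1, the smallest possible, adjusted p = 0.233). In deletion glucose the log2 ratios of actin, TBP and SRB4 were lower by 0.25, 0.37 and 0.33 and the rRNA controls higher by 1.04, in overexpression glucose the TBP ratio was higher by 0.85 and the spike-ins by 0.53, in deletion ethanol the spike-ins were higher by 0.38, and in overexpression ethanol the SRB4 ratio was higher by 0.72 and the rRNA controls lower by 0.66. The antisense spike-in probe sets were lower by 1.25 in overexpression glucose, 1.71 in deletion ethanol and 1.77 in overexpression ethanol, and by 0.60 in deletion glucose (exact permutation p = 0.4). The ratio of the 5′ to the 3′ probe set of the BioDn spike-in split the arrays in another way. It was 0.169 to 0.231 in the 6 wild type arrays and deletion glucose array 1, and 0.369 to 0.575 in the 11 others. Strain and this spike-in split are linked by that 1 deletion array only. The comparisons of each FAR1 strain with wild type also carry values with the split as a block, which all rest on that array.

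**Figure D2:**
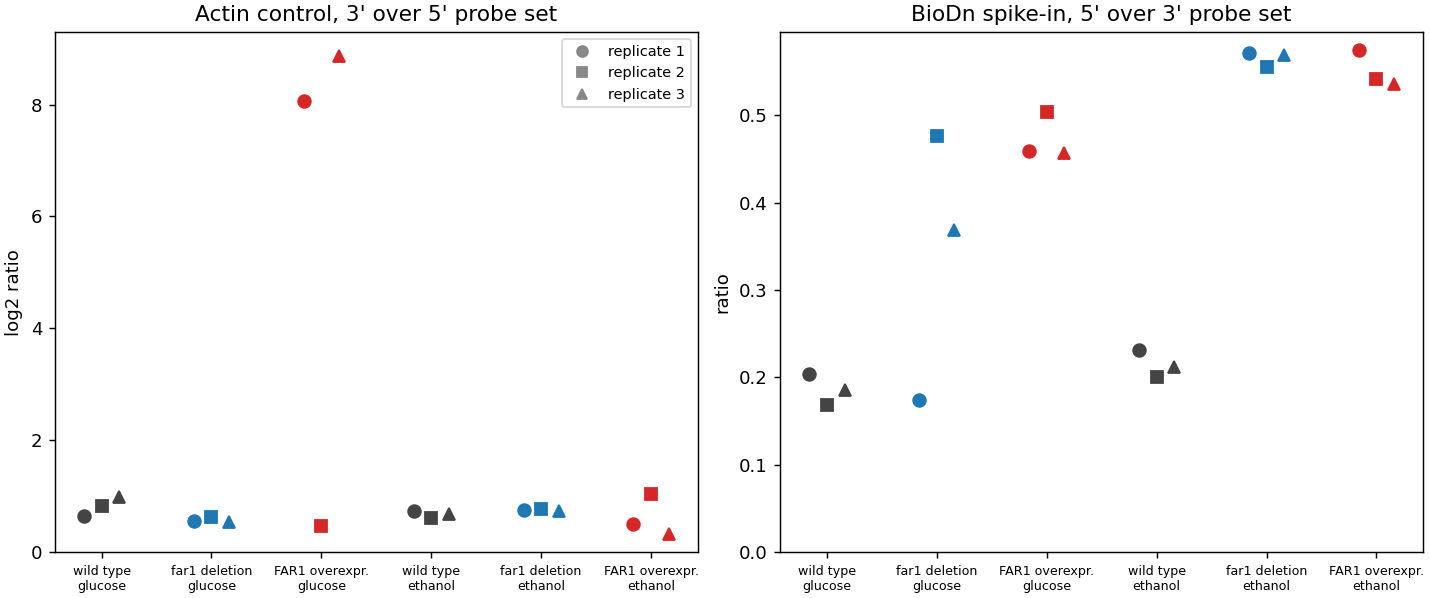
Left, log2 ratio of the 3′ to the 5′ actin probe set per array. Right, ratio of the 5′ to the 3′ BioDn spike-in probe set per array, by group, with marker shape for the replicate; overexpression glucose arrays 1 and 3 reach 8.06 and 8.87 on the left, and the wild type arrays lie at 0.169 to 0.231 on the right.

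All changes below are relative to the typical gene after quantile normalization. On the deposited scale the median log2 change of all genes was 0.40 for deletion in glucose, 0.49 for overexpression in glucose, 0.11 for deletion in ethanol and 0.07 for overexpression in ethanol. It was 0.66, 0.36 and 0.27 for ethanol against glucose in the wild type, deletion and overexpression strains. For the differences of the strain effects between carbon sources it was −0.30 in the deletion and −0.42 in the overexpression strain. With centred array medians the median change was −0.11 for ethanol against glucose in the deletion strain and closer to 0 in the other 8 comparisons.

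For the far1 deletion strain in glucose, camera placed the Gcn4 amino acid biosynthesis list above other genes and mitochondrial ribosomal proteins below them, and both calls were lost, at adjusted p = 0.842 with an estimated correlation. Singly 1 of 39 and 0 of 71 of their genes passed. Of the 39 Gcn4 changes 34 were positive, with a median log2 change of 0.27. MET13 of methionine synthesis rose by 1.43 ± 0.23 (adjusted p = 0.00245), and SAM3, an S-adenosylmethionine permease gene, by 1.03. The aromatic amino acid catabolism genes ARO10 and ARO9 fell by 2.73 ± 0.56 (adjusted p = 0.0174) and 2.01. Mitochondrial ribosomal protein genes had a median of −0.21, which became 0.24 on the deposited scale while the list stayed lower than other genes (adjusted p = 0.0134).

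Limma called 88 of 5545 genes in this comparison, 68 higher and 20 lower, of which 42 and 6 changed at least 2-fold. Beside HIS3 and TRP1, the largest rises were in CPD1 (2.45 ± 0.38, adjusted p = 0.00242), a cyclic phosphodiesterase gene, SPO21 (2.21), NDE2 (2.07), a mitochondrial NADH dehydrogenase gene, RFU1 (1.79) and SLF1 (1.76). CPD1, SPO21 and NDE2 read 0.1 to 1.1 in wild type glucose, near the floor of the scale, and with a pseudocount of 2.9 their changes were 1.01, 1.05 and 0.90 (adjusted p = 0.0875, which ended the NDE2 call). The largest falls beside ARO10 and ARO9 were in CYB2 (−1.23), a lactate dehydrogenase gene, HSP30 (−1.17), USO1 (−1.06), RGI1 (−0.98) and COA2 (−0.97). Absence of overlap between the groups was a condition for naming these largest changes, so it adds no evidence for them. Chance gives it in 10% of genes for 3 against 3 arrays. PDS5 fell by 0.90 and REC107 by 0.87. The ribosomal protein genes RPL17A and RPS0B rose by 0.69 and 0.65, with adjusted p = 0.0348 and 0.0347. ILV5 of branched-chain amino acid synthesis rose by 0.89 and ERG11 of ergosterol synthesis fell by 0.51. The cell cycle genes did not pass. Their log2 changes were −0.45 for CLN1, 0.30 for CLN2, 0.26 for CLN3, 0.09 for CLB5, −0.09 for CDC28 and −0.27 for SIC1. SFP1 changed by 0.35 (adjusted p = 0.361) and STE12, the pheromone response factor gene, by −0.53. The markers ADE2, LEU2, URA3 and CAN1 changed by −0.25, 0.57, −1.02 and 0.70 and did not pass.

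Camera called 7 of the 35 lists. Higher than other genes were Gcn4 amino acid biosynthesis (adjusted p = 8.63e-06, and adjusted p = 0.842 with an estimated correlation), methionine and sulfate (median 0.59, 0.00391, and adjusted p = 0.972 with an estimated correlation) and purine and one-carbon (median 0.27, 0.0342). Over all genes 1 of 39 Gcn4 genes, 2 of 25 methionine genes and 0 of 12 purine genes rose. These counts were 3, 3 and 0 when adjusted over the list alone. Lower than other genes were mitochondrial ribosomal proteins (2.14e-05), ribosome biogenesis (0.0187), ergosterol (0.0187) and G1/S targets (0.0304). The purine list and these 4 lists had adjusted p = 0.842 with an estimated correlation. The medians of ribosome biogenesis, ergosterol and G1/S targets were −0.13, −0.13 and −0.16, but 0.32, 0.35 and 0.24 on the deposited scale, where those 3 calls were lost. Of the 125 biogenesis genes 1 rose and of the 71 mitochondrial ribosomal protein genes 0 passed, by both adjustments. Over all genes 1 ergosterol gene fell and 1 G1/S gene rose, and adjusted over the list alone 2 ergosterol genes fell, and 2 G1/S genes rose while 1 fell. The remaining lists had adjusted p from 0.111 to 0.974.

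Methionine and sulfate lost its call without wild type array 2 (median 0.04, 0.395) or deletion array 3 (0.29, 0.176), and against the wild type mean the median of the list was −0.20, −0.70 and 0.97 in the wild type arrays and 0.11, 0.35 and 1.19 in the deletion arrays. The count was 29 without deletion array 1, 31 without wild type array 2, 48 without deletion array 2 and 43 with only the 2 groups, and it was 139 (138 higher) on the deposited scale. With the spike-in split as a block this comparison reduces to deletion array 1 against the wild type arrays. It therefore cannot decide whether the calls hold. The medians were then 0.36 for Gcn4 amino acid biosynthesis, 0.11 for methionine and sulfate and 0.31 for purine. They were −0.20 for mitochondrial ribosomal proteins, −0.18 for ribosome biogenesis, −0.21 for ergosterol and −0.23 for G1/S targets.

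For FAR1 overexpression in glucose, camera placed respiratory, stress and storage carbohydrate lists above other genes and ribosome biogenesis below them, and these calls were lost, at adjusted p = 0.266 to 0.598 with an estimated correlation. Singly 13 of 36 respiratory, 8 of 28 stress and 4 of 15 storage genes were higher and 7 of 125 biogenesis genes lower. Stress genes controlled by Msn2 and Msn4 had a median log2 change of 0.53, with TMA10 up by 1.68 ± 0.21 (adjusted p = 1.31e-04), DDR2 by 1.24 and TFS1 by 1.07. Genes of the respiratory chain and ATP synthase had a median of 0.47, with INH1, which codes for an ATP synthase inhibitor, up by 2.01 ± 0.28 (adjusted p = 3.66e-04), COX6 by 0.90 and COX4 by 0.95. Ribosome biogenesis genes had a median of −0.19, with UTP5 down by 1.64, NOP4 by 0.82 and PRP43 by 0.80; the median was 0.29 on the deposited scale while the list stayed lower than other genes (0.0221). Of the 3 arrays of this group, 2 lacked actin 5′ signal. Fits without these 2 keep 1 array of the group, which is assumed to vary like the other groups and decides nothing by itself.

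Limma called 403 genes, 294 higher and 109 lower, of which 124 and 49 changed at least 2-fold. Beside HIS3 and TRP1 the largest rises were CPD1 (3.28 ± 0.38, adjusted p = 7.20e-05), NDE2 (2.91), GAC1 (2.44), a glycogen regulator gene, and SPG4 (1.86). In wild type glucose these 4 read 0.1 to 2.1, near the floor of the scale, and with a pseudocount of 2.9 their changes were 1.59, 1.44, 1.14 and 0.92 (adjusted p = 0.0546, which ended the SPG4 call). SWI4, which codes for the DNA-binding part of the G1/S factor SBF, rose by 1.74 ± 0.23 (3.61e-04). The glycogen genes GPH1 and GLC3 rose by 1.06 and 0.68, and the hexose kinase genes HXK1 and GLK1 by 0.84 and 0.67. MET13 rose by 1.03 and SWI5 by 0.82. CMR1 fell by 3.56 ± 0.49 (3.66e-04), YAP7 by 2.89, CTF19 by 2.88 and ADA2 by 2.03. CMR1 and CTF19 read 0 to 0.4 in this group, and with a pseudocount of 2.9 their changes were −1.61 and −1.16. COB, a mitochondrially encoded cytochrome gene, fell by 2.70. The acid phosphatase gene PHO5 fell by 1.82, ILV1 by 0.81, RPL7A by 0.88 and ERG11 by 0.49. CLN3, a G1 cyclin gene, read 0.2, 194 and 0.2 in this group. Its log2 change of −4.29 (adjusted p = 0.0415) became 0.71 (0.667) without arrays 1 and 3. YAP7 read 0.3, 21.7 and 1.1 against 15.8 to 19.1 in wild type, and its change became −0.39 (0.801) without those arrays, where RPL7A was at −0.46 (0.592) and COX4 at 0.58 (0.278). CLN1, CLN2, CLB5, CDC28 and SIC1 changed by −0.07, 0.41, 0.21, 0.22 and −0.18 and did not pass. SFP1 changed by 0.23 (adjusted p = 0.460), STE12 by −0.70, ADE2 by −0.04, LEU2 by 0.61, URA3 by −0.19 and CAN1 by 0.17.

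Camera called 6 lists. Msn2/Msn4 stress genes (1.65e-07) had 8 of 28 genes higher over all genes and 14 adjusted over the list alone, with adjusted p = 0.266 with an estimated correlation. Respiratory chain and ATP synthase (1.38e-06) had 13 of 36 and 17, and storage carbohydrates (median 0.46, 6.94e-04) had 4 of 15 and 7, each with adjusted p = 0.598 with an estimated correlation. Ribosome biogenesis (2.27e-09) had 7 of 125 genes lower and 1 higher, by both adjustments, with adjusted p = 0.266 with an estimated correlation. Phosphate (median −0.25, 0.00458) had 1 of 13 genes lower by both adjustments, with adjusted p = 0.810 with an estimated correlation, and its median was 0.08 on the deposited scale, where it stayed lower than other genes (9.33e-05). Ergosterol (median −0.09, 0.0357) had 2 of 24 lower by both adjustments, with adjusted p = 0.598 with an estimated correlation, and its median was 0.41 on the deposited scale, where the call was lost. The remaining lists had adjusted p from 0.0646 to 0.957, with cytosolic ribosomal proteins at 0.591.

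Without the 2 arrays lacking actin 5′ signal, 62 genes passed, 31 higher and 31 lower, of which 40 were among the 403, HIS3, TRP1, CPD1, NDE2, SWI4, DDR2, TMA10, TFS1, CMR1, UTP5 and ILV1 included, and all called lists but ergosterol (0.0592) were called again, with adjusted p = 0.783 to 0.880 with an estimated correlation. Singly 0 of 36 respiratory, 3 of 28 stress and 0 of 15 storage genes were then higher and 2 of 125 biogenesis genes lower, and the respiratory median was 0.28. With the spike-in split as a block 23 passed, 14 of them among the 403, all 6 lists kept their calls and RNA polymerase I and III, translation factors and hexose transporters were called as well (each with adjusted p = 0.350 to 0.839 with an estimated correlation), the deposited scale gave 910 (875 higher), centred medians 411 (217 higher) and only the 2 groups 64, and the count was 170 without wild type array 2, 247 without wild type array 1, 187 without overexpression array 1, 187 without overexpression array 3 and 654 without overexpression array 2.

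In ethanol the arrays labelled deletion differed from wild type in few single genes. Of the 39 Gcn4 amino acid biosynthesis changes 37 were positive, with a median log2 change of 0.35, and 1 passed. Camera called the list, and the call was lost, at adjusted p = 0.299 with an estimated correlation. The arginine biosynthesis genes ARG1 and ARG7 rose by 1.20 ± 0.20 (adjusted p = 0.0288) and 0.97 ± 0.17 (0.0395), and with HIS3 and TRP1 they were the 4 called genes. Without the pair of doubtful arrays both arginine genes had adjusted p = 0.0521. URA3 changed by −1.89 (adjusted p = 0.216), SFP1 by −0.13 and STE12 by −0.03. CLN1, CLN2, CLN3, CLB5, CDC28 and SIC1 changed by 0.02, 0.03, −0.49, −0.15, 0.24 and −0.20, and ADE2, LEU2 and CAN1 by 0.36, 0.47 and 0.63. None of these passed.

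Camera called 12 lists in this comparison. The higher ones were Gcn4 amino acid biosynthesis (1.90e-18, and adjusted p = 0.299 with an estimated correlation), purine and one-carbon (median 0.11, 0.00532), heat shock proteins and chaperones (0.15, 0.0261), Msn2/Msn4 stress genes (0.12, 0.0368), and methionine and sulfate (0.35, 0.0368). The next 4 after Gcn4 had adjusted p = 0.613 to 0.762 with an estimated correlation, and the heat shock median was −0.01 with centred medians, where the call was lost. Over all genes 1 Gcn4 gene rose, and adjusted over the list alone 11 Gcn4, 2 purine and 2 heat shock genes rose. The lower lists were iron uptake (−0.24, 0.00457), cytosolic ribosomal proteins (−0.12, 0.0151), the G2/M CLB2 cluster (−0.20, 0.0167), G1/S targets (−0.12, 0.0351), mitochondrial ribosomal proteins (−0.12, 0.0368), histones (−0.42, 0.0368) and proteasome (−0.14, 0.0368). These had adjusted p = 0.566 to 0.736 with an estimated correlation. On the deposited scale the medians of G1/S targets, mitochondrial ribosomal proteins and proteasome were 0.02, 0.04 and 0.0071, and their calls were lost. Among iron genes 2 fell when adjusted over the list alone. The remaining lists had adjusted p from 0.0694 to 0.935.

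Without the doubtful pair 6 genes passed, among them FAR1, URA3 (−2.55) and, chosen after their values were seen, PHM8 (2.76, adjusted p = 0.00270) and FUR1 (1.82), and the calls of cytosolic ribosomal proteins (0.244), mitochondrial ribosomal proteins (0.642), histones (0.379), heat shock (0.161) and proteasome (0.208) were lost while Gcn4 amino acid biosynthesis kept its call (median 0.43, 7.63e-20, and adjusted p = 0.408 with an estimated correlation) with 0 of 39 genes passing. In that fit phosphate was called higher (0.40, 0.00179), as was the respiratory chain (0.0472), and M/G1 targets (0.0108) and uracil biosynthesis (0.0241) were called lower, with adjusted p = 0.555 to 0.886 with an estimated correlation. With the spike-in split as a block 7 genes passed, 2 higher and 5 lower, 2 of them among the 4, and of the 12 lists only Gcn4 amino acid biosynthesis (median 0.54, 1.63e-13) and proteasome (0.0223) kept their calls, while hexose transporters (0.43, 0.00569) were called higher and phosphate (−0.58, 0.0223) lower, these 4 with adjusted p = 0.710 with an estimated correlation, and methionine and sulfate turned to −0.18 (0.644). The gene count was 2 on the deposited scale, with centred medians, without the pair lacking actin 5′ signal, and without wild type array 2 or 3 or deletion array 1.

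In the arrays labelled overexpression in ethanol, camera placed the amino acid, methionine and purine biosynthesis lists above other genes and 4 cell cycle lists below them, and these calls were lost, at adjusted p = 0.187 to 0.331 with an estimated correlation. Singly 4 of 39 Gcn4, 0 of 25 methionine and 1 of 12 purine genes rose, and 0 genes of the G1/S, M/G1, G2/M and histone lists passed. All 25 measured methionine and sulfate genes had positive changes, with a median log2 change of 1.46. Against the wild type mean the median of this list was 0.19, 2.07 and 1.91 in arrays 1, 2 and 3 of the group, and that of Gcn4 genes 0.05, 0.55 and 0.46, where array 3 is 1 of the doubtful pair. HIS4 rose by 1.41 ± 0.25 (adjusted p = 0.0245), ARG1 by 1.20, HOM3 by 1.18 and LYS1 by 1.22, and ADE17 of purine synthesis rose by 1.79 ± 0.34 (0.0254). G1/S targets had a median of −0.22, the G2/M CLB2 cluster −0.25 and histones −0.39. The lipid synthesis genes OLE1, PSD1 and ACC1 fell by 1.03, 1.05 and 0.90.

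Limma called 22 genes, 13 higher and 9 lower, of which 11 and 4 changed at least 2-fold. Other rises were OPT1 (2.30 ± 0.45, adjusted p = 0.0317), an oligopeptide transporter gene, ATG41 (2.17), PCL5 (1.69) and RTS3 (1.56). Other falls were CMR1 (−2.34 ± 0.49, 0.0420), ADA2 (−1.69), PRP43 (−0.89), TRA1 (−0.80), PET127 (−0.78) and PHO3 (−0.66). SFP1 changed by −0.44 (adjusted p = 0.325), CLN1 by −0.37, CLN2 by 0.08, CLN3 by −0.35, CLB5 by −0.01, CDC28 by 0.27, SIC1 by −0.20 and STE12 by −0.22, and none passed. ADE2, LEU2, URA3 and CAN1 changed by 0.10, −1.04, −1.32 and 0.86 and did not pass.

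Camera called 15 lists. Higher were methionine and sulfate (2.94e-20), Gcn4 amino acid biosynthesis (median 0.33, 2.59e-10), purine and one-carbon (0.39, 2.57e-05), Msn2/Msn4 stress genes (0.27, 2.57e-05), stationary phase (0.41, 0.00210) and cell wall integrity (0.17, 0.00398). The first 5 had adjusted p = 0.187 with an estimated correlation, and cell wall integrity had adjusted p = 0.344 with an estimated correlation. Over all genes 0 methionine, 4 Gcn4 and 1 purine genes rose, and 1 biogenesis gene fell. When adjusted over the list alone 19 of 25 methionine, 10 of 39 Gcn4, 3 of 12 purine, 6 of 28 Msn2/Msn4 and 3 of 11 stationary phase genes rose, and 1 Gcn4 gene fell. Lower were G1/S targets (0.00171), M/G1 targets (−0.20, 0.00171), the G2/M CLB2 cluster (0.00210), ergosterol (−0.14, 0.00246), mitochondrial ribosomal proteins (−0.17, 0.00473), iron uptake (−0.19, 0.0111), histones (0.0186), glycolysis and fermentation (−0.25, 0.0210) and ribosome biogenesis (−0.11, 0.0228). These 9 had adjusted p = 0.187 to 0.619 with an estimated correlation. The biogenesis median was 0.0015 on the deposited scale, where its call was lost. Of the lower lists, 2 G1/S, 2 G2/M, 1 ergosterol, 2 iron, 1 histone and 2 biogenesis genes fell, adjusted over the list alone, while 1 glycolysis gene rose. The remaining lists had adjusted p from 0.124 to 0.975.

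Without the doubtful pair 111 genes passed, 59 higher and 52 lower, all 22 among them. In that fit, with genes chosen after their values were seen, CDC42 and HUG1 rose by 3.02 each, the pheromone response genes SST2 and PRM5 by 1.85 and 1.70, ENO2 of glycolysis fell by 1.91 and CLB1, a mitotic cyclin gene, by 1.05. The pheromone response list was then called higher (median 0.27, 0.00231, and adjusted p = 0.0725 with an estimated correlation), and methionine and sulfate kept its call (1.16, 1.13e-08, and adjusted p = 0.400 with an estimated correlation) with 0 genes past the test adjusted over the list alone. There iron uptake lost its call (0.0531), and cytosolic ribosomal proteins (−0.14, 0.0192) and phosphate (−0.27, 0.0180) were called lower, the latter 2 with adjusted p = 0.453 with an estimated correlation. With the spike-in split as a block 7 genes passed, 2 higher and 5 lower, 2 of them among the 22, the calls of mitochondrial ribosomal proteins (0.359), stationary phase (0.0857), glycolysis (0.261) and iron uptake (0.682) were lost, the other 11 lists kept theirs (methionine and sulfate at 0.99, 5.07e-05, and all 11 with adjusted p = 0.313 to 0.491 with an estimated correlation) and 5 further lists were called, phosphate (−0.72, 1.73e-04) the first of them, with adjusted p = 0.313 to 0.399 with an estimated correlation. There were 8 genes on the deposited scale, 7 with centred medians, 2 without the intensity trend and 9 with only the 2 groups. Leaving out wild type array 1, 2 or 3 gave 3, 2 and 2 genes, and leaving out overexpression array 1, 2 or 3 gave 68, 2 and 57.

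**Figure D3:**
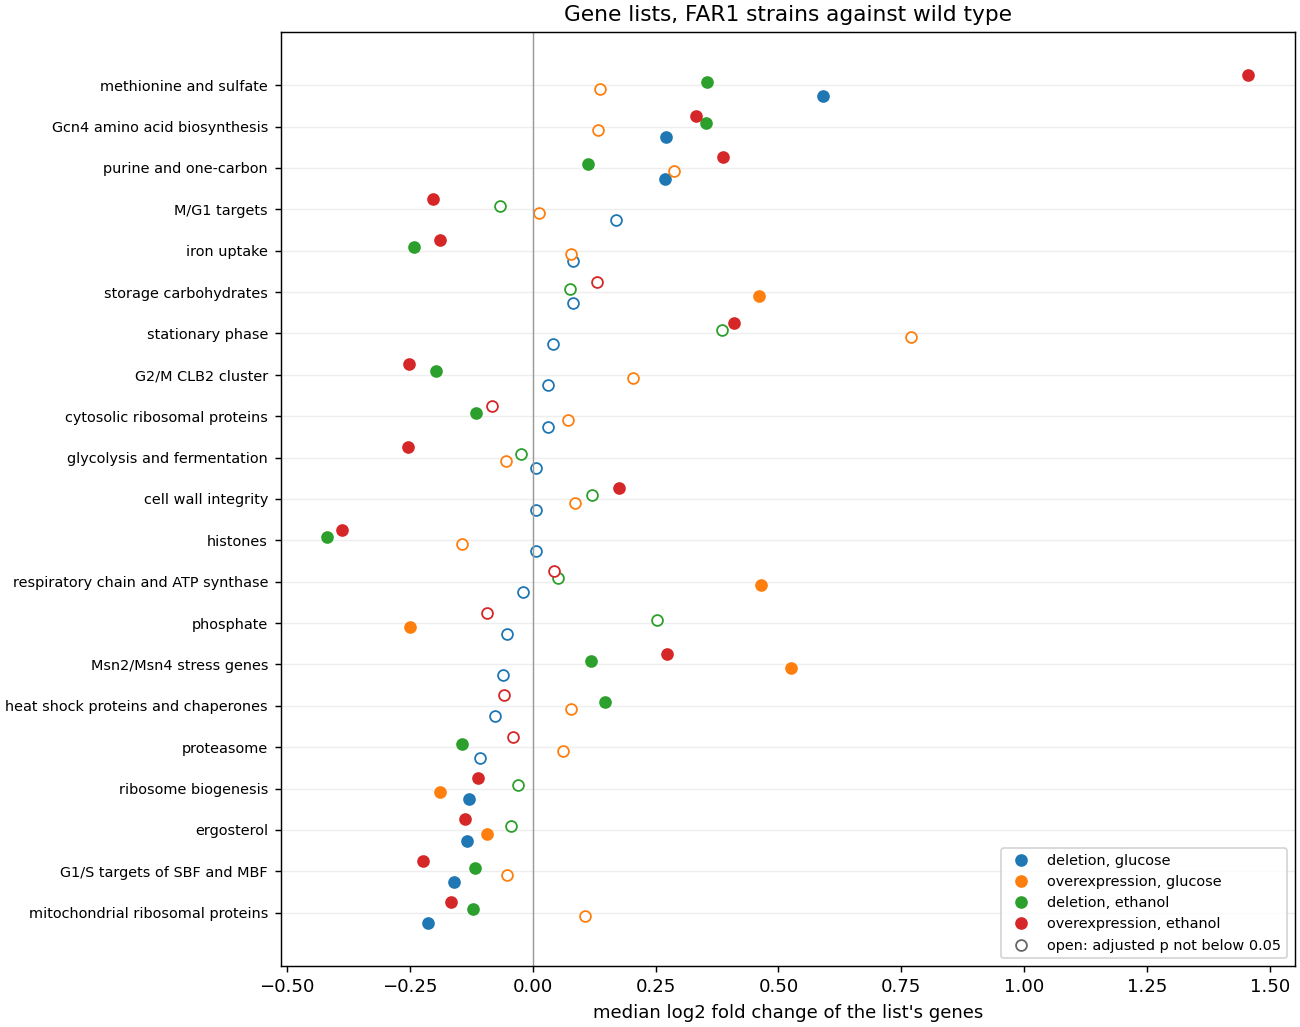
Median log2 change against wild type of each gene list called in at least 1 of the 4 strain comparisons, after quantile normalization; filled points are lists called by camera. Methionine and sulfate in overexpression ethanol has the highest median, 1.46, and several medians below 0 turn positive on the deposited scale, such as ribosome biogenesis in overexpression glucose (−0.19 to 0.29).

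Changes in the deletion and overexpression strains overlapped, although FAR1 dosage differed in opposite directions in glucose and, without the doubtful pair, in ethanol. With the arrays as labelled, the mean FAR1 change in ethanol was above 0 in both strains, at 1.01 and 3.89, and neither passed. In glucose, 55 genes were higher than wild type in both strains, against 3.61 expected for independent lists. A further 7 were lower in both against 0.393, and 0 were opposite. The log2 changes correlated across genes at r = 0.514. Shared wild type arrays alone gave a mean r of 0.500 in simulation, while the covariance was 0.117 against 0.0425 simulated. Without the 2 arrays lacking actin 5′ signal, which leaves 1 overexpression array, r was 0.591 against 0.355 simulated. In ethanol r was 0.611, against 0.503 simulated, and the covariance was 0.0785 against 0.0427, with 4 genes higher in both strains. Without the doubtful pair r was 0.432 against 0.397 simulated and the covariance 0.0621 against 0.0396, with 2 genes higher in both, HIS3 and TRP1, and FAR1 opposite. The 3 wild type arrays were not divided between the comparisons, since 1 side would keep a single array, so part of each overlap may come from the shared arrays. The spike-in split also sets the wild type apart. With it as a block r was 0.745 in glucose against 0.785 simulated, and 0.84 in ethanol against 0.85. The covariance was 0.321 against 0.169 in glucose and 0.272 against 0.233 in ethanol. In glucose the deletion effect is then that of deletion array 1 alone. The overexpression changes in glucose and ethanol correlated at r = 0.258, with 5 genes higher and 4 lower in both, against 0.689 and 0.177 expected. These were 16 and 9 without the doubtful pair, against 3.55 and 1.08 expected, and 3 and 0 without the arrays lacking actin 5′ signal. The deletion changes in glucose and ethanol correlated at r = 0.201, with 2 genes higher in both, HIS3 and TRP1, and none lower. Without the doubtful pair 4 were higher and 2 lower in both.

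Ethanol against glucose gave more called genes in each strain, 2226 to 2404, than either FAR1 strain did against wild type, at most 403. In the wild type, genes of gluconeogenesis, the glyoxylate cycle and ethanol use rose in 22 of 22 cases, with a median log2 change of 7.03. MLS1 and ICL1 of the glyoxylate cycle rose by 9.31 ± 0.34 and 8.09 ± 0.17, and the gluconeogenesis genes FBP1 and PCK1 by 8.51 and 7.56. Respiration rose with them, in 16 of 16 tricarboxylic acid cycle genes and 35 of 36 respiratory chain and ATP synthase genes. The low-affinity glucose transporter genes HXT1 and HXT3 fell by 5.94 ± 0.26 and 5.61 ± 0.21. Ribosome biogenesis genes fell in 114 of 125 cases, with a median of −1.04.

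Limma called 2404 genes, 1242 higher and 1162 lower, of which 654 and 424 changed at least 2-fold, and 2484 in the fit without the doubtful pair. Adjusted p-values of the genes named here lay below the threshold, at 3.10e-13 for MLS1 and 2.92e-13 for HXT3. The lactate transporter gene JEN1 rose by 8.84, the acetate transporter gene ADY2 by 8.22, SFC1 by 8.57 and STL1 by 7.55. The peroxisomal genes CTA1, POT1 and FOX2 rose by 7.03, 2.97 and 2.88. Stress genes such as HSP30 (5.88), DDR2 (5.63) and TMA10 (4.02) rose too, as did SDH2 (3.57), COX6 (2.27) and COX5A (2.28). COX5B, the hypoxic form of that last subunit, fell by 3.39. The repressor genes MIG2 and MIG3 fell by 4.11 and 4.05, ADH1 by 2.21, PDC1 by 1.58 and CDC19 by 2.18. MF(ALPHA)2 fell by 7.10, with intensities of at most 5.1 in ethanol and at least 234 in glucose over all strains. NSR1 fell by 1.97, ARG3 by 2.82, HIS1 by 2.07 and MET16 by 3.05. SST2, a pheromone response regulator gene, fell by 3.79. MLS1, near the floor, rose by 8.46 with a pseudocount of 2.9. CLN1 rose by 0.95 (adjusted p = 2.67e-04) and SFP1 by 0.45 (0.0397). STE12 fell by 1.13 (0.00275). CLN2 changed by 0.29, CLN3 by 0.79, CLB5 by −0.28, SIC1 by 0.18, CDC28 by −0.01 (0.73 on the deposited scale, adjusted p = 0.0184) and FAR1 by −0.72 (0.823), without passing.

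Camera called 22 lists, 10 of which kept their call with an estimated correlation. Of these 10, ribosome biogenesis (3.45e-28, with 118 of 125 lower adjusted over the list alone), RNA polymerase I and III (19 of 27 lower, 2.26e-07), translation factors (25 of 31 lower, 2.98e-06), cytosolic tRNA synthetases (17 of 18 lower, 9.71e-08) and alpha cell specific genes (4 of 4 lower, 4.98e-05) were lower than other genes. The RNA polymerase median was −0.61, but 0.07 on the deposited scale, where the list stayed lower than other genes. Gluconeogenesis (2.99e-26), tricarboxylic acid cycle (median 2.50, 3.88e-16), respiratory chain (1.81, 1.68e-20), fatty acid oxidation and peroxisome (2.50, 12 of 13 higher, 4.21e-08) and Msn2/Msn4 stress genes (1.66, 22 of 28 higher, 2.43e-11) were higher. Lists called higher whose call was lost were mitochondrial ribosomal proteins (40 of 71 higher, median 0.51, with adjusted p = 0.287 with an estimated correlation), storage carbohydrates (13 of 15, 1.80, adjusted p = 0.0559 with an estimated correlation), stationary phase (7 of 11, 1.93, adjusted p = 0.107 with an estimated correlation), cell wall integrity (8 of 15, 0.65, adjusted p = 0.287 with an estimated correlation) and M/G1 targets (9 of 22, 0.34, adjusted p = 0.287 with an estimated correlation). Lists called lower whose call was lost were Gcn4 amino acid biosynthesis (33 of 39 lower, −1.18, adjusted p = 0.107 with an estimated correlation), uracil biosynthesis (6 of 7, −1.27, adjusted p = 0.107 with an estimated correlation), glycolysis and fermentation (10 of 20, −0.48, adjusted p = 0.149 with an estimated correlation), methionine and sulfate (14 of 25, −1.41, adjusted p = 0.560 with an estimated correlation), hypoxic and anaerobic (5 of 9, −0.86, adjusted p = 0.120 with an estimated correlation), cytosolic ribosomal proteins (24 of 81, −0.19, adjusted p = 0.537 with an estimated correlation) and ergosterol (12 of 24, −0.33, adjusted p = 0.200 with an estimated correlation). The ergosterol median was 0.28 on the deposited scale, where the list stayed lower than other genes (0.0364). When adjusted over the list alone, the counts differed by at most 4 genes from these in every list. Lists not called had adjusted p of 0.0754 for iron uptake, 0.0865 for purine, 0.255 for sporulation, 0.259 for histones, 0.268 for pheromone response, 0.326 for G1/S targets, 0.381 for growth regulators, 0.428 for hexose transporters, 0.593 for a cell genes, 0.690 for heat shock, 0.758 for the G2/M cluster, 0.829 for phosphate and 0.979 for proteasome. On the deposited scale 2372 of 2546 called genes were higher, against 51.7% higher after quantile normalization and 43.0% with centred medians.

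The same carbon source response was measured in the deletion strain, whose ethanol array 3 is in doubt. Limma called 2380 genes, 1205 higher and 1175 lower, of which 633 and 440 changed at least 2-fold, and 2117 without the doubtful pair. Of the wild type calls 950 were higher and 883 lower here too, against 269.9 and 246.2 expected for independent lists, and 3 were opposite, and without the pair these numbers were 922, 810 and 0. MLS1 rose by 9.63, JEN1 by 9.48, SPG4 by 8.97, CRC1 by 8.95 and SFC1 by 8.59. MF(ALPHA)2 fell by 7.36, HXT1 by 6.05, HXT3 by 5.33 and HMS2 by 5.21. CLN1 rose by 1.43 (adjusted p = 3.79e-06), CDC28 by 0.32, and CLB5 fell by 0.52, while SFP1 changed by −0.03 without passing. Camera called 20 lists, and 8 held with an estimated correlation. The 8 were gluconeogenesis (22 of 22 higher, median 6.84), tricarboxylic acid cycle (16 of 16, 2.69), respiratory chain (35 of 36, 1.97), fatty acid oxidation (12 of 13, 2.47), Msn2/Msn4 stress genes (22 of 28, 1.83), ribosome biogenesis (111 of 125 lower, −0.96), RNA polymerase I and III (22 of 27 lower, −0.72) and alpha cell specific genes (4 of 4 lower, −2.22). The other 12, with adjusted p = 0.0598 to 0.518 with an estimated correlation, were cytosolic ribosomal proteins, translation factors, tRNA synthetases, glycolysis, Gcn4, methionine, uracil and hypoxic genes on the lower side and mitochondrial ribosomal proteins, stationary phase, storage carbohydrates and cell wall genes on the higher side. The counts adjusted over the list alone differed from those over all genes by at most 7 in any list. On the deposited scale 1478 of 1854 called genes were higher.

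In the overexpression strain limma called 2226 genes between ethanol and glucose, 958 higher and 1268 lower, of which 508 and 433 changed at least 2-fold, and 2107 without the doubtful pair. Of the wild type calls 778 were higher and 878 lower here too, against 214.6 and 265.7 expected, and 10 were opposite, and without the pair these numbers were 733, 872 and 17. MLS1 rose by 8.97, SFC1 by 8.55, JEN1 by 8.18, ADH2 by 7.90 and ADY2 by 7.89. MF(ALPHA)2 fell by 7.72, HXT3 by 5.92, HXT1 by 5.47 and ARI1 by 4.24. CLN1 rose by 0.66 (adjusted p = 0.00607) and CLB5 fell by 0.50, while SFP1 changed by −0.22 without passing. LEU2 fell by 2.31 and URA3 by 1.76. CLN3 rose by 4.72 (adjusted p = 0.00500) with all arrays and changed by −0.28 (0.704) without the 2 glucose arrays lacking actin 5′ signal. FAR1 changed by −1.34 (0.663), and rose by 1.91 (1.48e-05) without the doubtful ethanol pair. Camera called 19 lists, and 10 held with an estimated correlation. These were gluconeogenesis (22 of 22 higher, median 6.32), tricarboxylic acid cycle (16 of 16, 2.13), respiratory chain (35 of 36, 1.40), fatty acid oxidation (12 of 13, 2.19), Msn2/Msn4 stress genes (20 of 28, 1.37), and on the lower side ribosome biogenesis (113 of 125, −0.94), RNA polymerase I and III (21 of 27, −0.84), translation factors (17 of 31, −0.53), tRNA synthetases (18 of 18, −0.96) and alpha cell specific genes (4 of 4, −2.26). The other 9, with adjusted p = 0.0593 to 0.439 with an estimated correlation, were cytosolic ribosomal proteins, glycolysis, Gcn4, uracil and ergosterol genes on the lower side and mitochondrial ribosomal proteins, stationary phase, storage carbohydrates and cell wall genes on the higher side. List counts adjusted over the list alone differed by at most 4 from those over all genes. Without the 2 arrays lacking actin 5′ signal 1328 genes passed, 1232 of them among the 2226, with 619 higher and 557 lower as in the wild type, and on the deposited scale 1115 of 1452 called genes were higher.

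**Figure D4:**
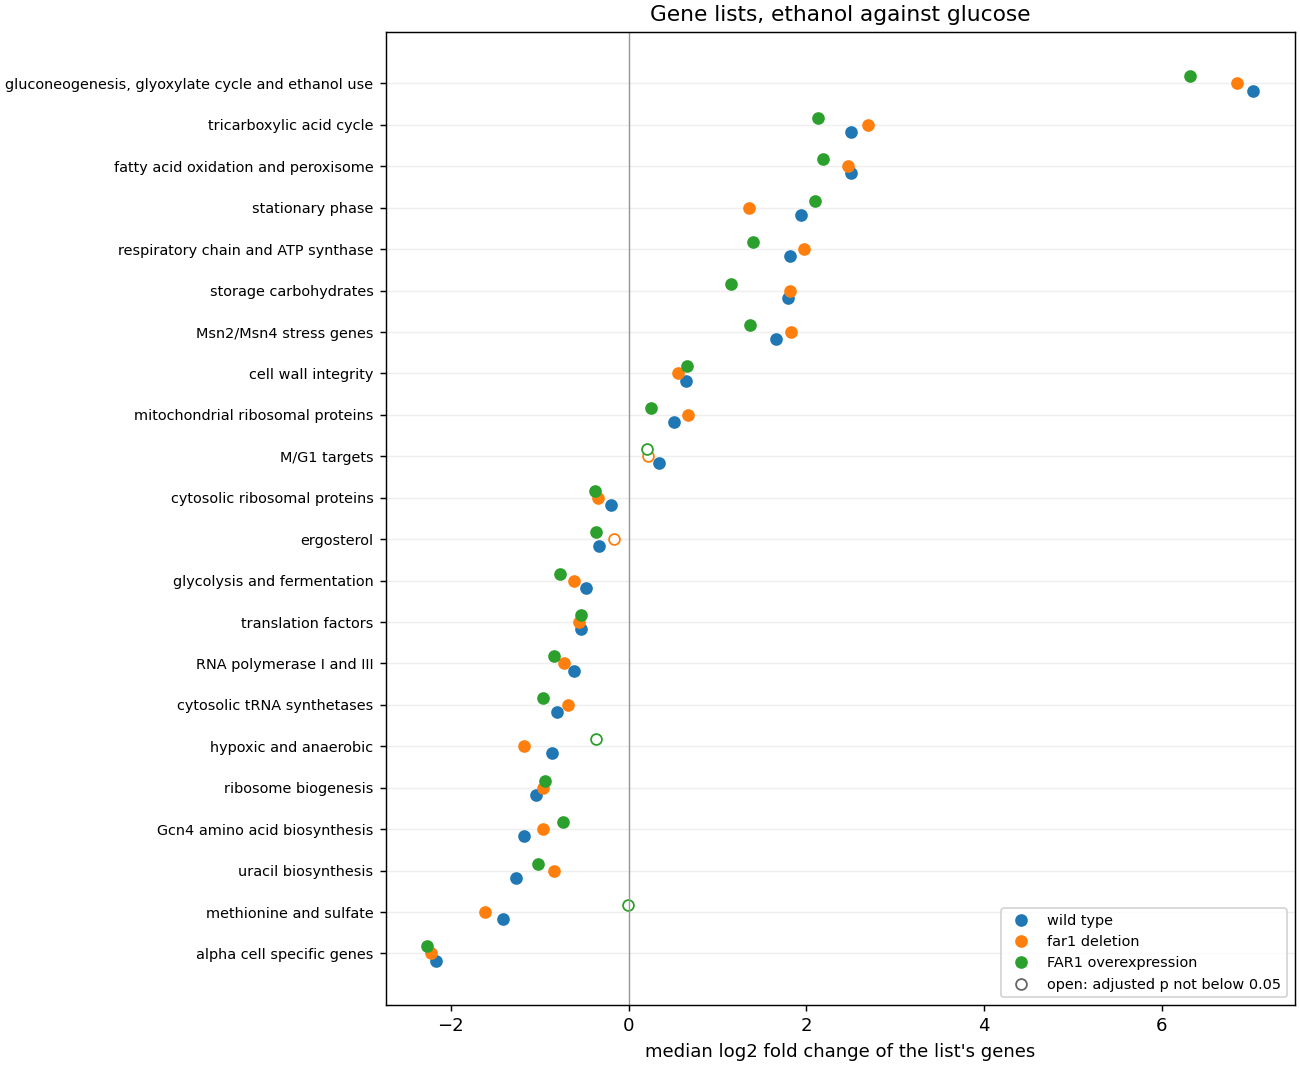
Median log2 change between ethanol and glucose of each gene list called in at least 1 of the 3 strains, after quantile normalization; filled points are lists called by camera. Gluconeogenesis medians are 7.03, 6.84 and 6.32 and ribosome biogenesis medians −1.04, −0.96 and −0.94; in the wild type the medians of RNA polymerase I and III and of ergosterol, −0.61 and −0.33, turn to 0.07 and 0.28 on the deposited scale.

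Whether a FAR1 strain's effect differed between ethanol and glucose was tested directly. For the overexpression strain 10 genes passed, 1 higher and 9 lower in ethanol relative to glucose. DLD3, a lactate dehydrogenase gene, had a difference of 2.71 ± 0.48 (adjusted p = 0.0221). NDE2 had −3.37 ± 0.56 (0.0213), STL1 −2.38, XDJ1 −1.62, NFS1 −1.26 and DDR2 −1.26. For the deletion strain limma called 0 genes, with 466 at unadjusted p under 0.05, and 0 genes without the doubtful pair. SFP1 had differences of −0.67 (adjusted p = 0.238) in the overexpression and −0.48 (0.619) in the deletion strain. NDE2 read 0.1, 1.1 and 0.4 and STL1 0.1, 0.5 and 0.1 in wild type glucose, at the floor of the scale, with STL1 at 0.7 to 1.4 in overexpression glucose. Their differences were −1.89 (0.0359) and −1.28 (0.0851) with a pseudocount of 2.9, which ended the STL1 call.

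Of the lists, methionine and sulfate (median 1.25, 9.92e-10), Gcn4 amino acid biosynthesis (0.32, 4.10e-04), phosphate (0.24, 0.0348) and ribosome biogenesis (0.07, 4.26e-04) were higher in ethanol relative to glucose for overexpression, and respiratory chain (−0.43, 4.26e-04), the G2/M CLB2 cluster (−0.49, 0.00167) and mitochondrial ribosomal proteins (−0.25, 0.0348) lower. The G2/M cluster had adjusted p = 0.442 and the other 6 0.815 to 0.828 with an estimated correlation. Methionine medians by array were 0.06, −0.39 and 1.01 in overexpression glucose and 0.19, 2.07 and 1.91 in ethanol, the last from a doubtful array. The Gcn4 and ribosome biogenesis medians were −0.08 and −0.31 on the deposited scale. Over all genes 1 biogenesis gene was lower, and adjusted over the list alone 2 Gcn4 genes were higher and 1 lower, and 7 respiratory chain and 2 G2/M genes lower. For deletion, heat shock proteins and chaperones (0.18, 0.00786) and gluconeogenesis (0.27, 0.0363) were higher, with deposited-scale medians of −0.16 and −0.16. Iron uptake (−0.21, 0.00942) and cytosolic ribosomal proteins (−0.13, 0.0174) were lower. These 4 had adjusted p = 0.823 to 0.830 with an estimated correlation. Over all genes 0 of their members passed, and adjusted over the list alone 2 heat shock genes and 1 gluconeogenesis gene were higher and 1 iron gene lower. No called list of any comparison had a median, a mean and a test of different sign.

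Without the doubtful ethanol pair 45 genes passed for overexpression, 18 higher and 27 lower, all 10 among them, the phosphate call (0.642) was lost, and glycolysis (−0.31, 0.00198) and cytosolic ribosomal proteins (−0.19, 0.0153) were called lower and pheromone response (0.0436) higher, the last with a median of −0.03. In that fit the deletion difference lost the calls of cytosolic ribosomal proteins (0.982) and gluconeogenesis (0.285), while mitochondrial ribosomal proteins (0.22, 5.11e-05) and Msn2/Msn4 stress genes (0.26, 0.0174) were called higher and M/G1 targets (−0.28, 0.0184) lower, and these 6 gained lists had adjusted p = 0.203 to 0.787 with an estimated correlation. For overexpression the calls of mitochondrial ribosomal proteins (0.496) and phosphate (0.0538) were lost, glycolysis was called lower (0.0398, and adjusted p = 0.839 with an estimated correlation) and 2 genes passed without the 2 arrays lacking actin 5′ signal, of which DLD3 was 1 (3.61, adjusted p = 0.00520). The count of 10 became 1 on the deposited scale, 6 with centred medians, 2 with only the groups compared, 16 and 74 without wild type glucose arrays 1 and 3, 0 without wild type ethanol array 2 or 3 or overexpression ethanol array 2, 1 and 152 without overexpression glucose arrays 1 and 2, and 35 without overexpression ethanol array 1.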

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

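The tests of differences between carbon sources in this part were chosen before the data were examined, and the fits without doubtful arrays were added afterwards. The effect of FAR1 overexpression against wild type differed between ethanol and glucose in 10 genes by a direct test of the difference in limma. Among these, DLD3 had a log2 difference of 2.71, NDE2 −3.37, STL1 −2.38, XDJ1 −1.62, NFS1 −1.26 and DDR2 −1.26, where NDE2 and STL1 lay at the floor of the scale in wild type glucose and STL1 did not pass with a pseudocount of 2.9. Without the 2 ethanol arrays whose FAR1 signal opposes their label 45 genes passed, and without the 2 glucose arrays lacking actin 5′ signal 2 passed.

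By the same test, 7 gene lists differed for overexpression, with medians of 1.25 for methionine and sulfate, 0.317 for Gcn4 amino acid biosynthesis, 0.238 for phosphate, 0.0695 for ribosome biogenesis, −0.254 for mitochondrial ribosomal proteins, −0.435 for the respiratory chain and ATP synthase and −0.486 for the G2/M CLB2 cluster. By array the methionine median was −0.39 to 1.01 in glucose and 0.19 to 2.07 in ethanol. For the deletion strain 4 lists differed, with medians of −0.133 for cytosolic ribosomal proteins, 0.271 for gluconeogenesis, 0.178 for heat shock proteins and chaperones and −0.215 for iron uptake. Those 4 had adjusted p = 0.823 to 0.830 with an estimated correlation. On the deposited scale the medians of ribosome biogenesis, Gcn4, gluconeogenesis and heat shock genes had the opposite sign, at −0.31, −0.08, −0.16 and −0.16.

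Probe sets that match several genes or none were not part of the gene tests. In a fit of all non-control probe sets they held a signal above wild type in 6 probe sets for deletion in glucose, 31 for overexpression in glucose and 1 for overexpression in ethanol, and a signal below it in 3, 61 and 3. For deletion in ethanol there were 0 of either.

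Single outlying samples within the groups of 3 arrays were not tested.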

How the results depend on the processing

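The deposited scale, the spike-in block and the fits without either or both of the doubtful pairs of arrays were chosen after the data were seen, and all other settings before. For the results given as moved below the cause was not tested, except for the drop from 403 to 62 genes, weighed in the closing section. Fits without arrays and with only the groups compared also have fewer samples. The counts of genes for ethanol against glucose in the wild type and the deletion strain stayed within 1.5 times of 2404 and 2380 under all settings. Of the tests of named genes under settings chosen beforehand 7450 kept their side of the threshold, 546 lost and 12 gained it, and 0 reversed. Of the tests of called lists 1849 kept it, 231 lost it and 2 reversed. Under the settings chosen afterwards 2244 gene tests kept their side, 322 lost and 24 gained it and 10 reversed, while 499 list tests kept it, 56 lost it and 5 reversed. Signals near background limit the fold changes, since 1955 values were 0.

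On the deposited scale the gene counts were 139 for deletion in glucose, 910 for overexpression in glucose, 2 for deletion in ethanol, 8 for overexpression in ethanol, 1452 for carbon source in the overexpression strain and 1 for the overexpression difference. FAR1 in overexpression glucose then passed at 5.13 (adjusted p = 0.0429), 4 lists were called for deletion in ethanol, and in the wild type carbon comparison ERG26 turned to 0.17 (0.600) and CDC28 to 0.73 (0.0184). Centred medians gave 2 genes and 7 lists for deletion in ethanol, 7 genes for overexpression in ethanol, 2 lists for the deletion difference and 6 genes for the overexpression difference. With only the groups compared the gene counts were 43 for deletion in glucose, 64 for overexpression in glucose, 9 for overexpression in ethanol and 2 for the overexpression difference, 8 lists were called for the deletion difference, and FAR1 passed at −2.60 (9.28e-04) and 4.51 (5.51e-05) for deletion and overexpression in glucose. Without the intensity trend 2 genes passed for overexpression in ethanol. All non-control probe sets gave 1 for the deletion difference and 5 for the overexpression difference.

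With an estimated correlation 0 lists were called in the 4 strain comparisons and the 2 differences, and 10, 8 and 10 for carbon source in the wild type, deletion and overexpression strains. Fry called 0 lists for deletion in glucose, deletion in ethanol and the deletion difference, 3 for overexpression in ethanol and 1 for the overexpression difference.

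With the spike-in split as a block the gene counts were 36, 23, 7 and 7 for deletion and overexpression in glucose and then in ethanol. For deletion in ethanol 4 lists were called, for the deletion difference 9, and the methionine and sulfate list turned to −0.18 (0.644) for deletion in ethanol. The correlations of strain effects rose to 0.745 in glucose, 0.841 in ethanol, 0.656 for overexpression and 0.648 for deletion between carbon sources, from 0.514, 0.611, 0.258 and 0.201. With the block all 4 effects share 1 coefficient, and draws without any strain effect gave 0.785, 0.847, 0.694 and 0.589 in the same order.

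Without the 2 ethanol arrays whose FAR1 signal opposes their label, FAR1 passed at −2.59 (5.80e-06) for deletion in glucose, 4.56 (4.50e-09) for overexpression in glucose and 7.19 (2.47e-11) for overexpression in ethanol, and turned to −2.16 (1.85e-04) for deletion in ethanol. FAR1 also turned to 1.91 (1.48e-05) for carbon source in the overexpression strain and 2.63 (7.61e-04) for the overexpression difference. In deletion ethanol the medians of cytosolic and mitochondrial ribosomal proteins turned to 0.0290 (0.244) and 0.0237 (0.642), and the ethanol correlation was 0.432. There were 111 genes for overexpression in ethanol and 45 for its difference. Without the 2 arrays lacking actin 5′ signal there were 62 genes for overexpression in glucose, 1328 for carbon source in that strain, 2 for the overexpression difference, 2 for deletion in ethanol, and 4 lists for deletion in glucose. CLN3 turned to 0.71 (0.667) for overexpression in glucose and −0.28 (0.704) for carbon source in that strain. Without both pairs the counts were 77, 121 and 1391 for overexpression in glucose, in ethanol and by carbon source. FAR1 was then −2.54 (6.32e-06), 4.37 (1.22e-06), −2.12 (1.55e-04) and 7.16 (7.10e-11) in the 4 strain comparisons, 2.07 (1.42e-04) by carbon source and 2.79 (0.00288) for the difference. CLN3 was 0.72 (0.204) and −0.0804 (0.870), the 2 ribosomal protein medians 0.0284 (0.212) and 0.0243 (0.629), and the ethanol correlation 0.431.

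Leaving out each array in turn, where the lone pair left in a group is assumed to vary like the other groups, gave these ranges. Gene counts were 29 (without deletion glucose array 1) to 126 for deletion in glucose, with 31 without wild type glucose array 2 and 48 without deletion glucose array 2. They were 170 (without wild type glucose array 2) to 654 (without overexpression glucose array 2) for overexpression in glucose, with 247 without wild type glucose array 1 and 187 without overexpression glucose array 1 or 3. They were 2 (without wild type ethanol array 2 or 3 or deletion ethanol array 1) to 5 for deletion in ethanol, and 2 (without wild type ethanol array 2 or 3 or overexpression ethanol array 2) to 68 (without overexpression ethanol array 1) for overexpression in ethanol, with 3 without wild type ethanol array 1 and 57 without overexpression ethanol array 3. For the deletion difference they were 0 to 2 (without wild type ethanol array 1), with 1 without wild type glucose array 3. For the overexpression difference they were 0 (without wild type ethanol array 2 or 3 or overexpression ethanol array 2) to 152 (without overexpression glucose array 2), with 16 and 74 without wild type glucose arrays 1 and 3, 1 without overexpression glucose array 1 and 35 without overexpression ethanol array 1. By carbon source they were 2042 to 2208, 2084 to 2218 and 1840 to 2208 in the wild type, deletion and overexpression strains. Called lists numbered 3 (without deletion glucose array 1) to 8 for deletion in glucose, with 4 without wild type glucose array 2 or deletion glucose array 2. They numbered 5 to 10 (without wild type glucose array 1) for overexpression in glucose, 2 (without wild type ethanol array 3) to 11 for deletion in ethanol (7 without wild type ethanol array 2), 12 to 17 for overexpression in ethanol, 2 (without wild type ethanol array 3) to 9 (without deletion glucose array 1) for the deletion difference (8 without wild type glucose array 2 or 3 or wild type ethanol array 1) and 6 to 9 for the overexpression difference. FAR1 changes were −2.74 to −2.46 and 4.29 to 4.65 in glucose, and −2.17 (without deletion ethanol array 3) to 2.72 and 2.29 to 7.13 (without overexpression ethanol array 3) in ethanol. The correlations were 0.407 to 0.636 in glucose, 0.501 to 0.679 in ethanol, 0.198 to 0.275 for overexpression and 0.121 to 0.235 for deletion. The actin difference of 4.98 ranged from 3.45 to 7.65. For deletion in ethanol the medians of cytosolic and mitochondrial ribosomal proteins ranged from −0.19 and −0.15 to 0.0287 (0.228) and 0.0237 (0.668), the latter 2 without deletion ethanol array 3.

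Replicate numbers as a block gave 79, 356, 5 and 19 genes for the strain comparisons in glucose and then ethanol, 2347, 2348 and 2211 by carbon source, and 0 and 9 for the differences. Arrays with the same number gave no ground for this pairing, since 7 of 45 such pairs correlated above 0.1 after group means were removed, with a median r of 0.0017 and a range from −0.375 to 0.177.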

Other observations

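The tests of plasmid loss, of fewer arrays and of FAR1 overexpression below, and the 3 tests on Gcn4 genes, were chosen after their results had been seen. Related values, such as the control ratios and the counts without the doubtful pair, had been seen before some of the other tests were written. Single genes of lists that the main account treats only in passing, most of them not called as lists, also differed in ethanol. In the wild type, IME1, which codes for the inducer of meiosis, rose by 1.78 in ethanol, the cell wall glucan synthase gene GSC2 by 2.20, the siderophore-binding cell wall gene FIT3 by 1.84 and the G1 cyclin gene PCL1 by 1.17. TOR1, which codes for a nutrient-sensing kinase, rose by 0.90, and TOD6, a repressor of ribosome biogenesis genes, fell by 1.14. The alpha cell genes moved with carbon source in all 3 strains. SAG1, which codes for the alpha-agglutinin, fell by 2.86 and MF(ALPHA)1 by 1.46 in the wild type.

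Among the remaining a cell genes, BAR1 read 1.6 to 5.4, MFA2 1 to 11.4 and STE6 2.1 to 4.9 over the 18 arrays. SAG1 read 8.2 to 127.

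In overexpression glucose array 2 alone, set against wild type, HCM1 of the G1/S targets rose by 1.79 and the carboxypeptidase gene CPS1 by 1.76. DLD3 fell by 2.52, SYO1 by 2.49 and ESF1, of ribosome biogenesis, by 1.98. These genes were chosen after their values were seen, and the lone array is assumed to vary like the other groups.

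The FAR1 signal of 2 ethanol arrays opposed their labels. An error of the FAR1 probe set alone would leave other genes about evenly split, but 90 of the 100 genes that best separate the other 4 arrays had the opposite sign in the pair. Plasmid loss in the overexpression culture alone is argued against by a FAR1 intensity of 2595.7 in the array labelled deletion, where the highest wild type array read 29.3. An exchange of the 2 labels remains a candidate explanation. The difference between the 2 arrays correlated with that of the other 4 at r = −0.102 across 5543 genes. This lay just past the limit of −0.1 set beforehand. Arrays 1 and 2 gave 0.0559 and 0.157 in the same way. The arrays they were set against include the doubtful pair, so these 2 values are no clean reference for the −0.102. No other biological explanation was tested.

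Fewer genes passed for overexpression in glucose without the 2 arrays lacking actin 5′ signal, 62 in place of 403. Fewer arrays alone are argued against as the whole explanation, because 257 genes passed with only array 1 of the group and 365 with only array 3. Labelling biased to the 3′ end may contribute. The deviation of arrays 1 and 3 from array 2 had a rank correlation of −0.195 with gene length. In other groups the same value, of 2 arrays against the third, lay at −0.145 or above, except −0.574 for deletion ethanol array 3. That array is 1 of the doubtful pair, and the length test hinges on it, so the weight of the bias stays open. An effect of FAR1 overexpression stays open too, since 5 of the 6 lists were still called in the same direction with array 2 alone (with adjusted p = 0.783 to 0.880 with an estimated correlation), and 1 array decides nothing.

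The Gcn4 amino acid biosynthesis list was called above other genes in both FAR1 strains in ethanol, with 1 and 4 of 39 genes passing singly and both calls lost (adjusted p = 0.299 and 0.187 with an estimated correlation). A dosage effect in opposite directions stays open. Without the doubtful pair both medians lay above 0, the lower at 0.241, but the comparisons share their wild type arrays and both calls were lost again (adjusted p = 0.408 and 0.387 with an estimated correlation). The spike-in split stays open, since the median in deletion glucose was 0.363 with the split as a block, which rests on the 1 array that links strain and split. Intact HIS3 and TRP1 in both FAR1 strains may also contribute, as the lowest log2 difference from wild type was 3.61, and the design cannot tell apart marker genes and FAR1, whose dosage acting alike in both strains was not tested and remains open.

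The counts of called genes were also set against other splits of the same 6 arrays, fitted with only those arrays. A comparison of 3 against 3 arrays has 10 splits, which cannot give a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 43 and 1 for deletion in glucose, 64 and 0 for overexpression in glucose, 5 and 3 for deletion in ethanol, and 9 and 0 for overexpression in ethanol. For ethanol against glucose they were 2445 and 0 in the wild type, 2185 and 0 in the deletion strain and 2011 and 0 in the overexpression strain.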
